A study of Arabidopsis thaliana with 18 samples.

How the data were processed

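The data are 18 poly(A) RNA-seq libraries from whole Arabidopsis thaliana seedlings, 3 for each of 6 groups. The groups are the wild type (WT, accession Col-0), ahl10-1 and rrp6l1-2, each kept at control water potential or moved to low water potential, as the labels give them. Per the labels' protocols, RNA was poly(A)-selected and made into stranded libraries with a kit that marks the strand. The series' design text describes the 3 libraries of a group as separate biological experiments.

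The authors deposited 1 table per library. Per the file headers, each table gives, for 33602 loci, the deposited expected counts of reads, the deposited RPKM (reads scaled by gene length and library total), the deposited fraction of a gene's reads that map to several places, and other gene properties such as the length in kilobases. Between 3.92% and 4.56% of the genes of a library had counts that were not whole, so reads mapping to several places had been shared out between genes. The submitters' processing notes name TAIR10, CASAVA, bcl2fastq 1.8.4, Bowtie2 and DESeq2, without their roles. The counting tool and its strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be assigned with certainty. The authors also deposited 5 tables of their own comparisons, with, per the file headers, a log2 fold change and its standard error, a test statistic (a score), a p-value and an adjusted p-value, and other columns such as the mean of normalized counts. No column of per-sample values was left unused. The deposited RPKM were used only in 2 alternatives, and the deposited comparison tables only to set their calls beside those computed here.

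Library totals ran from 57996104 to 68555138 reads. A count of 0 allows a level of up to 3 reads, which is 0.0438 to 0.0517 CPM, the counts-per-million scale, in these libraries. This floor covers counting error only, since PCR copies are not independent molecules. Chloroplast genes took 0.102% to 0.589% of the reads, multi-mapped reads 1.25% to 2.33%, and the 10 most abundant genes 4.67% to 7.19%. A chi-square test of the counts of each of the 18 pairs of replicates gave 16.2 to 110 per gene, and 0 pairs were identical, so each library was counted as 1 replicate.

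Loci were named from NCBI's annotation of assembly TAIR10.1, in which 32835 of the 33602 loci have a locus tag. A further 488 nuclear, 133 chloroplast and 146 mitochondrial loci were not matched and keep their identifiers. Coordinates are those of TAIR10.1. The files carry no coordinates of their own.

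Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, then glmQLFTest). All 18 libraries entered 1 fit with 6 group means and no other covariate, which leaves 12 residual degrees of freedom. TMM factors, which lay between 0.901 and 1.072, scaled the libraries. filterByExpr by group kept 22795 genes, and 5697 loci had 0 reads in every library. The biological coefficient of variation was 14.4%. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with the standard error (SE) of the fit, and levels as TMM-scaled CPM with the standard deviation (SD) over 3 libraries. All adjusted p-values of single genes in the text come from this edgeR test unless another tool is named. The comparisons were stress against control in each of the 3 genotypes, each mutant against WT at each treatment, and the interaction of each mutant with stress. Principal components were computed on log2 CPM with a prior count of 2.

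Before the data were examined, the groups, the tests, 34 gene lists with 519 loci, the alternatives and the rule for naming genes were fixed. The lists were drawn from general knowledge of the genes and not from these libraries, and 495 of their symbols are in the RefSeq gene names. The lists were tested with camera in limma 3.58.1 with its preset correlation of 0.01, adjusted over the 34 lists of a comparison, and again with the correlation estimated from the data and with fry. Member counts are given over all genes tested and adjusted over the list alone. The rule named AHL10 and RRP6L1 in every comparison, the 5 annotated genes on each side of them, and up to 3 members of a list with the smallest adjusted p. It also took, per comparison, the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the 3 libraries of one group and the 3 of the other. For an interaction the overlap was not required. Genes named outside the rule are said to have been chosen after their values were seen.

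The same replicate numbers occur in all 6 groups, and the labels do not say what they share. Deviations from the group means over 14716 genes correlated above 0.1 in every pair of same-numbered libraries in 3 comparisons: rrp6l1-2 against WT at control (0.478, 0.338 and 0.158), ahl10-1 stress against control (0.365, 0.251 and 0.402) and rrp6l1-2 stress against control (0.51, 0.154 and 0.227). Libraries of different numbers correlated by at most 0.254, -0.00299 and 0.168 in these comparisons. Of the 3 numbers, 2, 3 and 2 correlated best with their own, so the pairing is less certain for rrp6l1-2. In these 3 comparisons the numbers were taken to pair the libraries, from the data rather than from the labels, and the fit with the replicate number as a block was set beside the one without it. That block is common to all 6 groups and does not pair the libraries of 1 comparison alone.

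The alternatives were DESeq2 1.42.0 (Wald test), RLE size factors or plain library sizes in edgeR, no expression filter beyond 1 read, a stricter filter of 1 CPM in 6 libraries, and a minimum log2 change of 1. Further ones were limma on log2(RPKM + 0.5) and log2(RPKM + 0.1) for genes with an RPKM of at least 1 in 3 libraries, the replicate block, a fit of only the groups compared, and leaving out each library in turn. Fits with fewer libraries kept the same genes, and TMM factors and dispersions were estimated again. Overlaps between the 2 mutants, which share the WT libraries, were set beside 40 simulations of unchanged mutants. Each simulated count, those of WT included, was drawn independently, so these simulations hold no structure common to many genes. Other splits of the libraries were all 10 for 3 against 3 libraries and 40 drawn for each interaction.

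The test was tested on simulated data with the means and library sizes of the 22795 genes. Changes were planted only in genes with a mean of at least 2 CPM, whereas the genes tested reached down to a mean log2 CPM of -4.27. The recoveries hold for those better expressed genes only. For ahl10-1 against WT at control it recovered 41 of 67 genes changed 1.5-fold, 61 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 13 false calls among 181. For the rrp6l1-2 interaction the numbers were 20 of 67, 47 of 67 and 63 of 66, with 2 false calls among 132. A simulated rrp6l1-2 against WT at control with no change gave 1 call, and a simulated ahl10-1 interaction with no change gave 0. In 1 planted list and 33 random lists, camera called the planted list and 0 of the random ones. The simulated genes were drawn independently, so this does not show how often camera falsely calls lists of correlated genes. In the real libraries another split of WT and ahl10-1 at control called 17 of the 34 lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.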

Results

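Transcripts were measured by poly(A) RNA sequencing in whole Arabidopsis thaliana seedlings of 3 genotypes. These were the wild type (WT, Col-0) and the mutants ahl10-1 and rrp6l1-2. AHL10 encodes a DNA-binding protein of the AT-hook family. RRP6L1 encodes a relative of the exosome-associated exonuclease RRP6. Seedlings grew on agar plates without sugar. They were transferred at 7 days of age to fresh control medium at a water potential of -0.25 MPa or to agar infused with polyethylene glycol (PEG) at -0.7 MPa. PEG of high molecular weight draws water from the tissue without entering the cells, and so imitates a drying soil. All seedlings were harvested 96 h later, at 11 days, and each of the 6 groups has 3 libraries from separate experiments, 18 in total. Each library holds 57996104 to 68555138 reads assigned to genes, and between 24067 and 24740 genes had at least 1 read. The design asks which transcripts change at low water potential, which change when AHL10 or RRP6L1 is disrupted, and whether the mutations alter the response to stress.

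Treatment separated the libraries along the first principal component, which held 50.5% of the variance, and the second held 8.33%. On the second component the 6 WT libraries lay below 0, and 10 of the 12 mutant libraries lay above it. The exceptions were ahl10-1 control replicate 1, at -32.73, close to WT control replicate 1 at -34.73, and ahl10-1 stress replicate 1, at -9.37. Replicate 1 was the lowest of its group on this component in every group except WT stress, as in rrp6l1-2 at control, with 10.31 against 29.15 and 35.67. The component therefore went with the replicate number as well as with genotype.

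**Figure D1:**
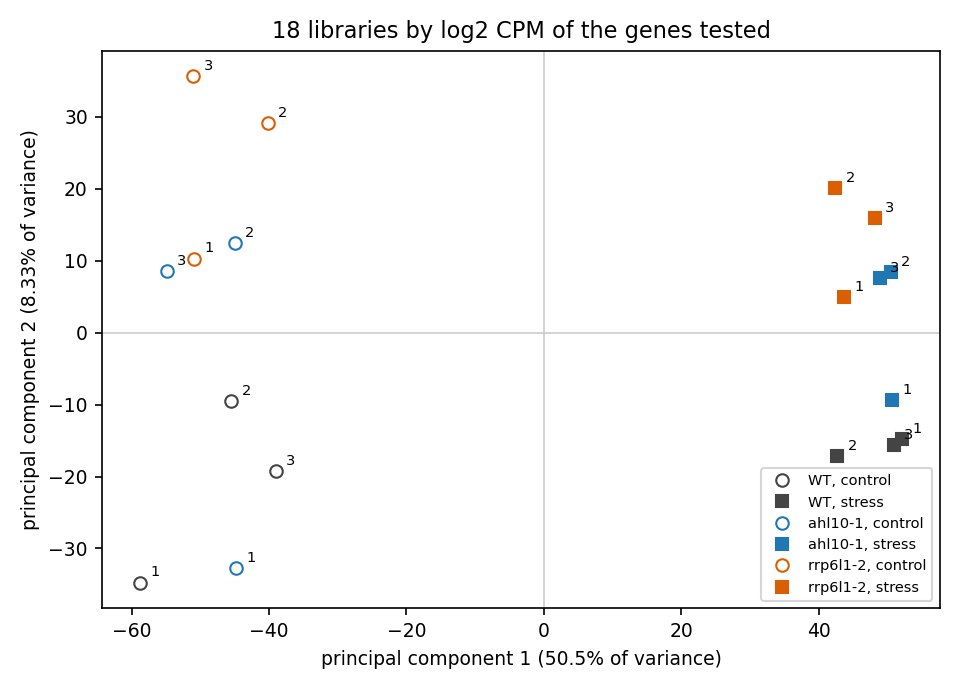
Position of the 18 libraries on the first and second principal components of log2 CPM, with the percent of the variance on each axis, open symbols for control, filled symbols for stress and the replicate number beside each point. Control and stress libraries lie on opposite sides of the first axis, and ahl10-1 control replicate 1 lies among the WT libraries on the second.

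AHL10 (AT2G33620, chromosome 2, 14234026 to 14236883) was lower in ahl10-1 than in every other library. Its level was 45.9 ± 0.706 CPM in WT at control and 63.2 ± 1.26 CPM at stress (mean ± SD, n = 3). In ahl10-1 it was 22.8 ± 2.34 and 29.7 ± 2.59 CPM, and in rrp6l1-2 it was 38.7 ± 1.67 and 59.5 ± 4.1 CPM. The 6 ahl10-1 libraries ran from 20.9 to 32.6 CPM and the 12 others from 36.9 to 64.6 CPM. Against WT the log2 fold change was -1.01 ± 0.0763 at control (edgeR adjusted p = 3.81e-06) and -1.09 ± 0.076 at stress (adjusted p = 1.61e-06). AHL10 itself rose at stress, by 0.46 ± 0.075 on the log2 scale in WT (adjusted p = 0.000293), by 0.38 ± 0.076 in ahl10-1 (adjusted p = 0.00138) and by 0.62 ± 0.0753 in rrp6l1-2 (adjusted p = 2.13e-05).

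RRP6L1 (AT1G54440, chromosome 1, 20322964 to 20328238) was lower in rrp6l1-2 than in every other library, at 3.67 to 8.97 CPM in its 6 libraries against 24.6 to 29.1 CPM in the 12 others. Its mean was 26.9 ± 1.45 CPM in WT at control and 28.4 ± 0.687 CPM at stress, 25.0 ± 0.753 and 27.5 ± 1.73 CPM in ahl10-1, and 7.23 ± 1.68 and 5.07 ± 1.39 CPM in rrp6l1-2. Against WT the log2 fold change was -1.90 ± 0.161 at control (adjusted p = 1.82e-05) and -2.49 ± 0.165 at stress (adjusted p = 6.96e-07). Stress left RRP6L1 at a log2 change of 0.07 ± 0.152 in WT (adjusted p = 0.762). Within rrp6l1-2 it was lower at stress by -0.51 ± 0.164 (adjusted p = 0.0274), a call that was lost without stress replicate 1 (-0.33), control replicate 2 (-0.53), stress replicate 2 (-0.52) or control replicate 3 (-0.34) of that line, and in a fit of those 6 libraries alone (-0.52). By replicate number RRP6L1 went from 5.63 to 3.67, from 7.09 to 5.09 and from 8.97 to 6.44 CPM in this line, and with the replicate block its call was kept. Counts per gene do not show which part of either transcript remained. AT2G33630 (14236833 to 14238877) overlaps the end of AHL10, and reads there cannot be assigned without the strand setting.

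**Figure D2:**
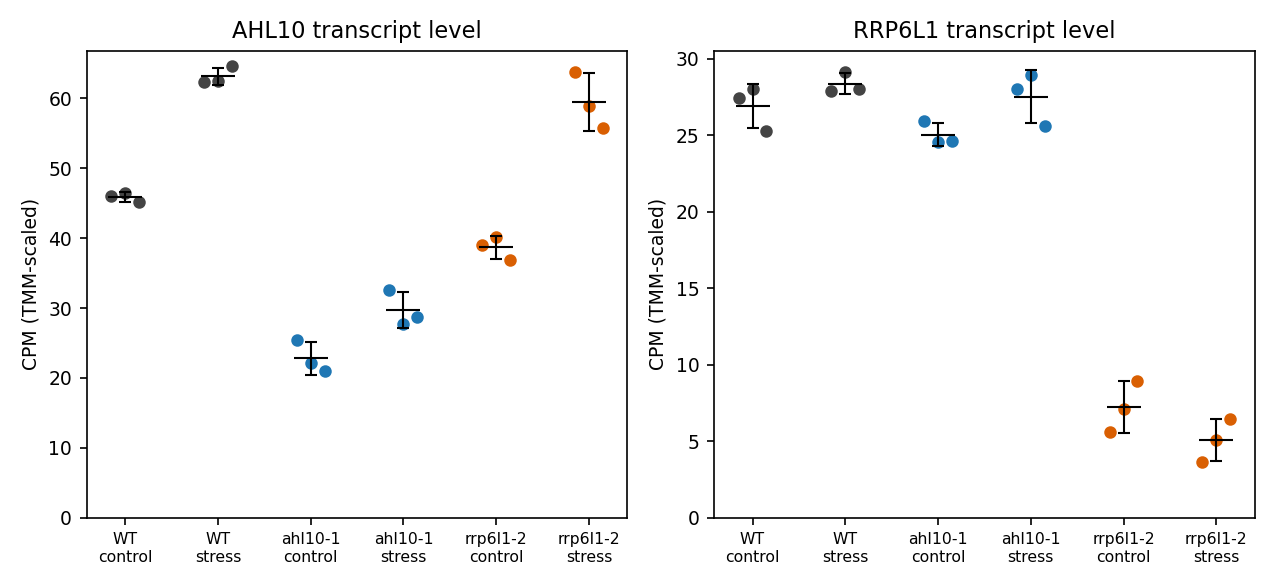
Level of AHL10 and of RRP6L1 in each of the 18 libraries in CPM, by genotype and treatment, with the mean and SD of 3 libraries as a dash and bar. AHL10 lies at 20.9 to 32.6 CPM in ahl10-1 and RRP6L1 at 3.67 to 8.97 CPM in rrp6l1-2, below all other libraries in each case.

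The 5 annotated genes on each side of each locus were examined next. Near AHL10 the 7 neighbours with enough reads were not called in ahl10-1 at control or at stress, among them CRL1, CRL2, SWI3B and AT2G33630 (smallest adjusted p = 0.793). Near RRP6L1 the level of 2 genes collapsed in rrp6l1-2. AT1G54410, which encodes a dehydrin of the KS type (chromosome 1, 20309473 to 20310850), was at 569 ± 27.8 CPM (mean ± SD, n = 3) in WT at control and 0.543 ± 0.0986 CPM in rrp6l1-2, a 1050-fold difference resting on 94 reads in the 3 mutant libraries. At stress it was at 614 ± 17.2 CPM against 2.78 ± 4.22 CPM, a 221-fold difference on 516 reads. AT1G54400 (20307572 to 20308846) had 0 reads in all 6 rrp6l1-2 libraries and 22 to 64 reads in each of the 12 others. It was therefore at least 32.3-fold lower than in WT at control and 46.5-fold lower at stress, against a floor of 3 reads over the group. The log2 fold change of AT1G54410 was -10.0 ± 1.00 at control (adjusted p = 0.00044) and -7.79 ± 0.876 at stress (adjusted p = 0.00143). The stress call was lost in a fit of the compared groups alone, at -7.80, and without rrp6l1-2 stress replicate 3, which held 7.66 CPM of AT1G54410, the stress change was -10.78. On the other side, AT1G54450 (20336203 to 20339769) was higher in rrp6l1-2, by 0.65 ± 0.113 at control (adjusted p = 0.0249) and 0.60 ± 0.112 at stress (adjusted p = 0.0741). AT1G54445, too low to be tested, had 45 reads over the rrp6l1-2 control libraries, 16 over the stress libraries and 0 in the 12 others. ING2, AT1G54460, RPP27 and XRN4 were not called in this line.

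**Figure D3:**
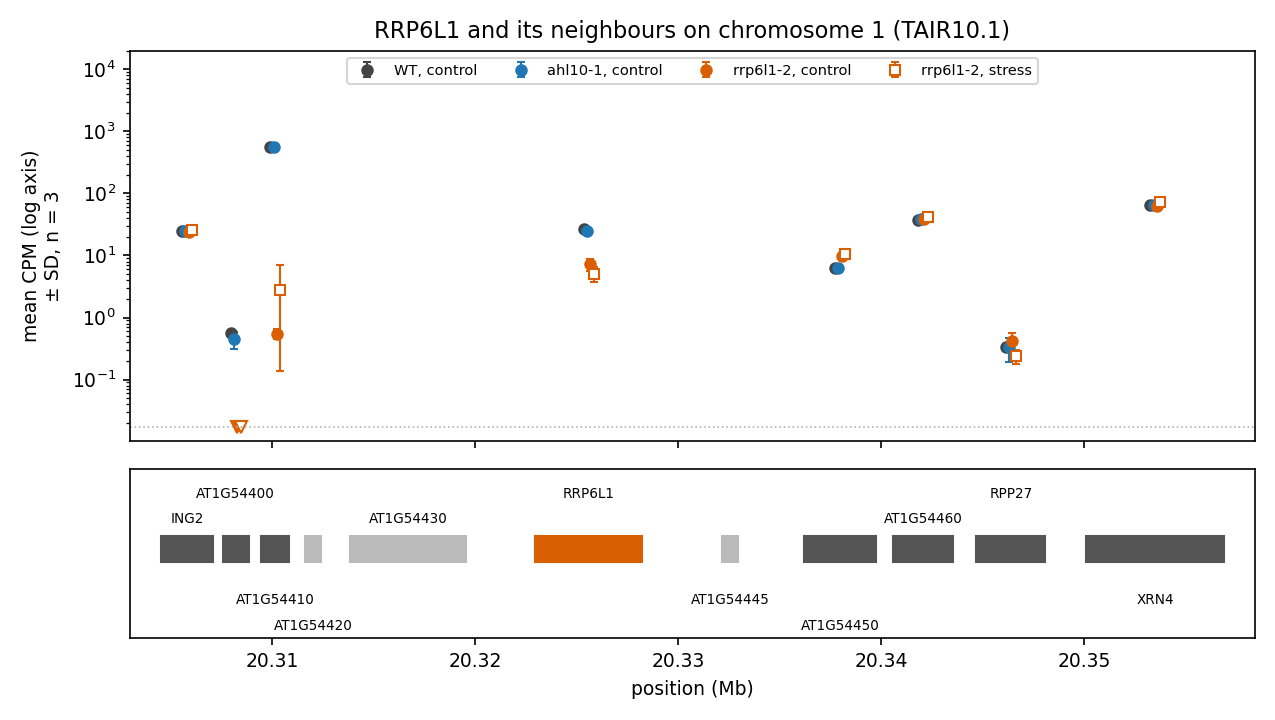
Upper panel, mean level on a log axis in CPM with SD (n = 3) of RRP6L1 and the tested genes among 5 annotated ones on each side. Shown are WT, ahl10-1 and rrp6l1-2 at control (filled) and rrp6l1-2 at stress (open squares). Lower bars are cut short where the SD is about as large as the mean or larger. Triangles on the dotted line mark tested genes with 0 reads in a group, drawn at the floor of 3 reads over the group. Lower panel, RRP6L1 in orange and all 5 annotated genes on each side on chromosome 1, tested genes dark and untested genes light. AT1G54410 lies at 569 CPM in WT and 0.543 CPM in rrp6l1-2 at control.

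In WT, low water potential changed 5941 of the 22795 genes tested. The largest rises were those of LTP4, a lipid transfer protein, by 6.90 ± 0.541 on the log2 scale (adjusted p = 1.3e-06), NUDT24, by 5.94 ± 0.772, the sugar transporter gene SAG29, by 5.54 ± 0.667, and AT2G37870, a lipid transfer family protein, by 5.06 ± 0.275. LTP4 went from 0.684 ± 0.643 to 80.4 ± 19.1 CPM. Among the largest falls were the receptor-like kinase gene CRK30, at -5.45 ± 0.397 (adjusted p = 3.55e-07), AT3G16670, of the pollen Ole e 1 and extensin family, at -5.13 ± 0.54, the extensin-like AT1G26250, at -4.51 ± 0.53, the leucine-rich repeat kinase gene AT5G59680, at -4.21 ± 0.28, and CYP71B22, at -4.02 ± 0.429. Of the 5941 genes, 2879 rose and 3062 fell, and 1630 changed at least 2-fold, 645 of them upward. In 5786 of the called genes the control and stress libraries did not overlap, as in 43.2% of all genes tested, where chance gives 10%.

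Genes of the response to dehydration and abscisic acid (ABA) rose together. Of 24 genes on the dehydration and ABA-induced list, 18 rose and 0 fell (19 and 1 adjusted over the list alone), with a median log2 change of 1.66; RD20 rose by 3.38 ± 0.177 and the homeobox gene HB7 by 2.08 ± 0.127. The list was called by camera (adjusted p = 2.99e-22) but not with an estimated correlation (adjusted p = 0.0507). Clade A PP2C phosphatases, which hold back ABA signalling, rose in 7 of 9 cases with 0 falls (the same adjusted over the list alone), led by HAI2 at 4.56 ± 0.292, HAI1 at 2.81 ± 0.281 and ABI2 at 1.25 ± 0.169 (camera adjusted p = 4.39e-09, and 0.0969 with an estimated correlation). ABA receptors moved the other way, with 9 of 11 lower and 0 higher (the same adjusted over the list alone), and PYL6 changed by -3.99 ± 0.335, PYL5 by -2.4 ± 0.205 and PYL4 by -2.31 ± 0.178. That list was called with both correlations (adjusted p = 3.47e-12 and 0.00323). Among 13 genes of ABA synthesis and turnover, 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0129, and 0.08 with an estimated correlation). The 3 with the smallest p were the glucosidase gene BGLU18, at 2.94 ± 0.373, and the ABA-degrading hydroxylases CYP707A4, at 1.1 ± 0.203, and CYP707A1, at 0.89 ± 0.183.

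The gene of the rate-limiting enzyme of proline synthesis, P5CS1, rose by 3.28 ± 0.142 on the log2 scale (adjusted p = 2.27e-09), from 73.3 ± 10.4 to 710 ± 66.6 CPM. OAT rose by 0.46 ± 0.0679 and P5CR by 0.37 ± 0.0863. Of 7 genes of proline synthesis and transport, 3 rose and 1 fell (4 and 2 adjusted over the list alone), and the list was called with both correlations (adjusted p = 0.000894 and 0.0417). The 2 proline dehydrogenase genes fell, PRODH1 by -1.54 ± 0.222 and PRODH2 by -1.52 ± 0.185, while P5CDH, which acts after them, rose by 0.74 ± 0.0594. The 3-gene breakdown list as a whole was not called (camera adjusted p = 0.413). Galactinol synthases, which start the synthesis of raffinose sugars, rose in part: GOLS2 by 2.44 ± 0.269 and GOLS4 by 1.4 ± 0.203, while the stachyose synthase gene STS changed by -1.73 ± 0.403. That list of 6, with 2 rises and 2 falls (3 and 2 adjusted over the list alone), was not called (adjusted p = 0.169).

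Flavonoid and anthocyanin genes rose in 9 of 15 cases with 0 falls (the same adjusted over the list alone), with a median of 2.79. The glucosyltransferase genes UF3GT, at 4.99 ± 0.523, and UGT75C1, at 4.18 ± 0.418, the transport gene GSTF12, at 4.51 ± 0.465, DFR, at 4.75 ± 0.554, and their MYB regulator PAP1_AT1G56650, at 4.96 ± 0.561, were among them (camera adjusted p = 1.68e-10, and 0.0762 with an estimated correlation). Of 12 xylem and secondary wall genes 9 rose and 1 fell (10 and 1 adjusted over the list alone), including the cellulose synthase genes CESA8 at 0.72 ± 0.0695, CESA4 at 0.81 ± 0.0946 and CESA7 at 0.84 ± 0.103 (camera adjusted p = 2.63e-07, and 0.239 with an estimated correlation). Jasmonate genes rose in 8 of 23 cases with 0 falls (the same adjusted over the list alone), and LOX2 changed by 2.99 ± 0.305 and VSP2 by 2.72 ± 0.18 (camera adjusted p = 0.000593, and 0.62 with an estimated correlation). Root hair genes rose in 4 of 13 cases (4 adjusted over the list alone), with COW1 at 1.12 ± 0.225 (camera adjusted p = 0.00742, and 0.637 with an estimated correlation). Of 22 cell cycle genes 7 rose (7 adjusted over the list alone), by little: the median was 0.15, CYCA1;1 rose by 0.41 ± 0.0847 and CDKB1;1 by 0.31 ± 0.0777 (camera adjusted p = 0.0129, and 0.637 with an estimated correlation).

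Auxin response and transport genes fell in 10 of 32 cases with 0 rises (the same adjusted over the list alone), among them IAA6 at -2.37 ± 0.388, IAA19 at -1.36 ± 0.158 and IAA3 at -0.96 ± 0.148 (camera adjusted p = 0.000729, and 0.62 with an estimated correlation). Genes of the rapid response to touch and wounding fell in 11 of 12 cases (11 lower and 1 higher adjusted over the list alone), with a median of -2.64 (camera adjusted p = 0.0114, and 0.637 with an estimated correlation). CML38 was at -3.79 ± 0.914 and lost its call in a fit of the WT libraries alone. The call of ZAT10, at -3.33 ± 0.88, was lost in the same fit and without WT control replicate 1 (-2.31) or WT stress replicate 1 (-3.29), and its level over the WT control libraries was 80.1 ± 72.4 CPM. Aquaporin genes fell in 6 of 19 cases and rose in 2 (7 and 3 adjusted over the list alone), with TIP2;1 at -1.43 ± 0.133, PIP1;5 at -1.15 ± 0.118 and PIP2;5 at 1.22 ± 0.139 (camera adjusted p = 0.0164, and 0.637 with an estimated correlation). Of 20 salicylate and defence genes 6 fell and 1 rose (9 and 1 adjusted over the list alone). WRKY54 changed by -1.78 ± 0.181 and WRKY18 by -1.05 ± 0.236, whereas the glucanase gene PR2 rose by 4.03 ± 0.714 (camera adjusted p = 0.00486, and 0.62 with an estimated correlation). Photosynthesis genes fell in 2 of 30 cases (2 adjusted over the list alone) with a median of -0.38 (camera adjusted p = 0.0114, and 0.726 with an estimated correlation). Those 2 were LHCA1, at -0.73 ± 0.201, and LHCB1.4, at -1.22 ± 0.336; both lost the call without WT control replicate 1 (-0.62 and -0.94) and LHCB1.4 also without WT stress replicate 3 (-1.13). Iron deficiency genes fell in 3 of 12 cases (4 adjusted over the list alone), including NAS4 at -1.02 ± 0.249 (camera adjusted p = 0.0429, and 0.637 with an estimated correlation).

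The lists not called in WT held members that changed in both directions or few that changed. Of 28 AHL family genes 2 rose and 3 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.74), among them AHL15 at -0.53 ± 0.0902. Of 17 genes of the RNA exosome and its cofactors 0 passed the edgeR test, over all genes or adjusted over the list alone (adjusted p = 0.776); the smallest adjusted p was that of RRP42, 0.0575 at -0.26. Wax genes went both ways, with 2 higher and 4 lower of 9 (2 and 6 adjusted over the list alone; adjusted p = 0.447), and CER1 rose by 1.86 ± 0.138 while CUT1 changed by -0.86 ± 0.109. Among 18 flowering regulators 1 rose and 5 fell (2 and 5 adjusted over the list alone; adjusted p = 0.119), with CO at -1.54 ± 0.227 and its target FT at -1.58 ± 0.239. Phosphate starvation genes rose in 6 and fell in 2 of 13 cases (6 and 3 adjusted over the list alone; adjusted p = 0.0903), with the phosphatase gene PAP17 at 1.85 ± 0.205. Of 27 expansins and xyloglucan endotransglucosylases 9 rose and 8 fell (the same adjusted over the list alone; adjusted p = 0.969), with XTH4 at -1.15 ± 0.103; the median of this list was 0.08 and its mean -0.15. Glucosinolate synthesis genes rose in 2 and fell in 4 of 17 cases (the same adjusted over the list alone; adjusted p = 0.402), with MAM3 at -1.22 ± 0.11, a median of 0.08 and a mean of -0.12.

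Carbon starvation genes fell in 2 of 6 cases (2 adjusted over the list alone; adjusted p = 0.0903), DIN10 by -2.72 ± 0.279 and SEN1_AT4G35770 by -3.17. Of 8 stomatal and guard cell genes 2 fell (2 adjusted over the list alone; adjusted p = 0.0903), the potassium channel gene KAT1 by -1.28 ± 0.141 and MYB60 by -0.99 ± 0.139. Of 11 clock genes 1 rose and 1 fell (1 and 3 adjusted over the list alone; adjusted p = 0.776), with ELF4 at 0.51 ± 0.0792. Of 20 meristem and boundary regulators 2 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.755), the fall being that of CLV1, at -0.72 ± 0.0766. Seed storage genes rose in 1 of 7 cases (1 adjusted over the list alone; adjusted p = 0.402), that of EM1 at 2.97 ± 0.641. MRU1 was the 1 of 6 loci under DNA-methylation silencing that fell (1 adjusted over the list alone; adjusted p = 0.288), by -0.89 ± 0.195. Type-A cytokinin response regulators fell in 2 of 10 cases (0 adjusted over the list alone; adjusted p = 0.485). Suberin and Casparian strip genes rose in 2 and fell in 1 of 14 (1 and 1 adjusted over the list alone; adjusted p = 0.195). Of the sulfur starvation genes 1 of 10 rose (1 adjusted over the list alone; adjusted p = 0.37).

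With plain library sizes in place of TMM factors, the split in WT moved from 48.5% to 60.4% of calls higher, and with limma on log2(RPKM + 0.5) or log2(RPKM + 0.1) to 61.0% and 60.8%. The authors' deposited table of this comparison called 6352 genes, 2981 higher and 3371 lower, and 5275 of them were called here in the same direction and 0 in the opposite one. Log2 fold changes in the authors' deposited table and in this test correlated with r = 0.969 across genes, which are not independent replicates.

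**Figure D4:**
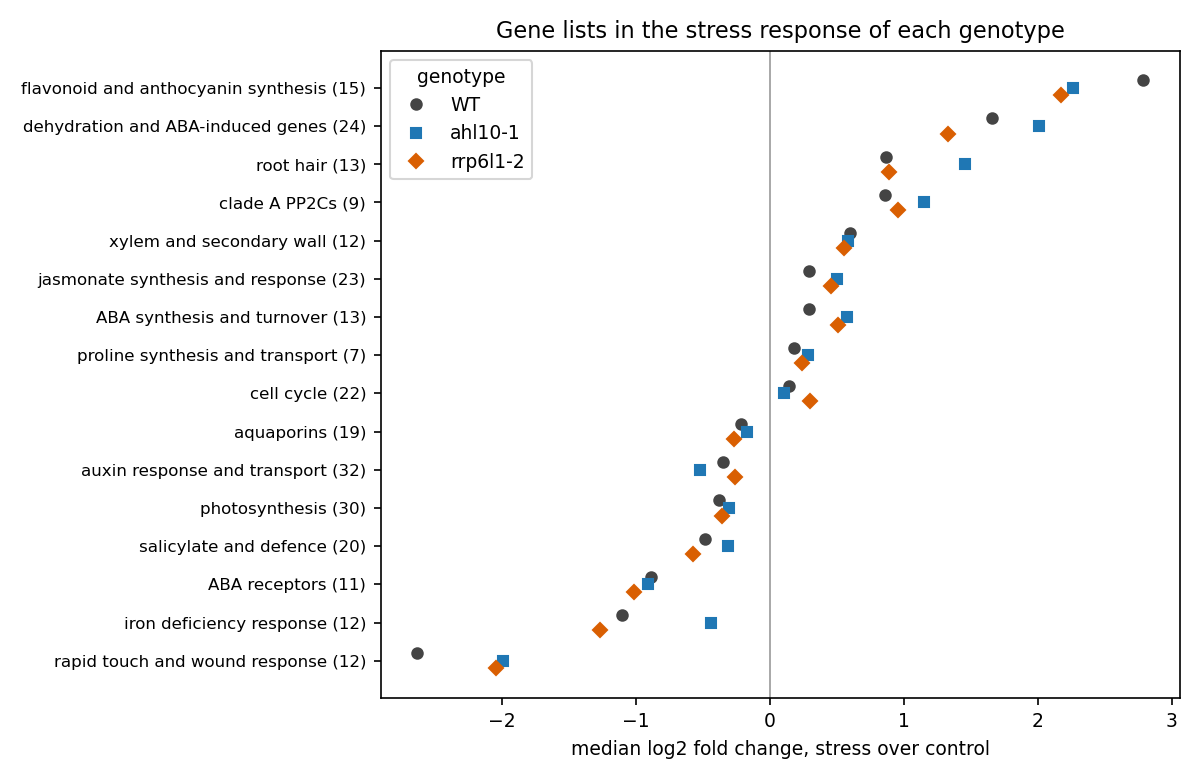
Median log2 fold change at stress against control, on the horizontal axis, of the 16 lists called in WT, for WT, ahl10-1 and rrp6l1-2, with the number of genes tested in brackets. The medians in WT run from -2.64 for touch and wound genes to 2.79 for flavonoid genes.

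The response to low water potential was then measured in ahl10-1. P5CS1 rose by 3.51 ± 0.143 on the log2 scale (adjusted p = 9.18e-10), from 75.0 ± 13.7 to 854 ± 27.8 CPM, LTP4 by 7.38 ± 0.559, HAI2 by 5.39 ± 0.312, the storage protein gene VSP2 by 3.24 ± 0.184 and GOLS2 by 3.09 ± 0.277. Among the largest falls were CRK30, at -5.18 ± 0.388, AT3G16670, at -5.28 ± 0.551, the transporter gene UMAMIT17, at -4.14 ± 0.187, and PYL6, at -4.11 ± 0.343, and PRODH1 changed by -1.95 ± 0.224. In all, 6861 genes changed, 3576 higher and 3285 lower, and 1723 changed at least 2-fold. In 6411 of them the groups did not overlap, as in 40.1% of the genes tested, where chance gives 10%.

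By list, 14 were called in ahl10-1, and 4 of them also with an estimated correlation. On the dehydration and ABA-induced list 22 of 24 genes were higher (22 adjusted over the list alone; adjusted p = 4.47e-25 and 0.0351). Of 11 ABA receptors 8 were lower (8 adjusted over the list alone; adjusted p = 4.85e-12 and 0.00209). Of 13 genes of ABA synthesis and turnover 8 were higher (8 adjusted over the list alone; adjusted p = 0.00433 and 0.0482). Of 7 genes of proline synthesis and transport 4 were higher and 1 lower (4 and 2 adjusted over the list alone; adjusted p = 0.000236 and 0.0265). For the other 10 lists the call was lost, and the adjusted p with an estimated correlation is given for each. Clade A PP2C genes rose in 7 of 9 cases (7 adjusted over the list alone; adjusted p = 0.0914). Flavonoid genes rose in 10 of 15 (11 adjusted over the list alone; adjusted p = 0.0941). Raffinose-family genes rose in 4 of 6 with 1 fall (the same adjusted over the list alone; adjusted p = 0.0941), and root hair genes in 11 of 13 (12 adjusted over the list alone; adjusted p = 0.575). Jasmonate genes rose in 11 of 23 cases and fell in 1 (11 and 2 adjusted over the list alone; adjusted p = 0.243). Xylem genes rose in 9 of 12 and fell in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.356). Auxin genes fell in 14 of 32 cases (16 adjusted over the list alone; adjusted p = 0.452). Aquaporins fell in 7 of 19 with 3 rises (the same adjusted over the list alone; adjusted p = 0.585). Salicylate genes fell in 7 of 20 with 1 rise (the same adjusted over the list alone; adjusted p = 0.575) and photosynthesis genes in 4 of 30 (0 adjusted over the list alone; adjusted p = 0.765). With plain library sizes the split moved from 52.1% to 63.0% of calls higher, and with limma on log2(RPKM + 0.5) or log2(RPKM + 0.1) to 64.0% and 63.8%.

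In rrp6l1-2, P5CS1 rose by 3.31 ± 0.142 (adjusted p = 1.97e-09), to 745 ± 64.4 CPM, LTP4 by 7.03 ± 0.558, HAI2 by 5.61 ± 0.327, VSP2 by 2.80 ± 0.18 and GOLS2 by 3.08 ± 0.28. CRK30 changed by -5.00 ± 0.376, UMAMIT17 by -3.81 ± 0.185, AT5G59680 by -4.14 ± 0.275 and PRODH1 by -1.57 ± 0.222. In all, 6733 genes changed, 3388 higher and 3345 lower, and 1556 changed at least 2-fold. In 6499 of them the groups did not overlap, as in 44.7% of the genes tested, where chance gives 10%.

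Cell cycle genes rose in 13 of 22 cases in rrp6l1-2 (17 adjusted over the list alone), among them CYCB2;1 at 0.75 ± 0.141 and CYCA1;1 (AT1G44110) at 0.50 ± 0.0851 (camera adjusted p = 8.5e-05, and 0.542 with an estimated correlation). Of the 14 lists called, only ABA receptors, with 8 of 11 lower (9 adjusted over the list alone), held with an estimated correlation (adjusted p = 0.00299). For the others the adjusted p with an estimated correlation is given. Dehydration genes rose in 17 of 24 cases (18 adjusted over the list alone; adjusted p = 0.112) and PP2C genes in 7 of 9 (7 adjusted over the list alone; adjusted p = 0.178). Flavonoid genes rose in 8 of 15 (8 adjusted over the list alone; adjusted p = 0.251), root hair genes in 2 of 13 (2 adjusted over the list alone; adjusted p = 0.668) and jasmonate genes in 9 of 23 with 1 fall (the same adjusted over the list alone; adjusted p = 0.524). Proline synthesis and transport genes rose in 4 of 7 and fell in 2 (4 and 3 adjusted over the list alone; adjusted p = 0.0663). Xylem genes rose in 9 of 12 and fell in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.362). Falls were called in 8 of 32 auxin genes (8 adjusted over the list alone; adjusted p = 0.668) and 6 of 19 aquaporins against 3 rises (9 and 3 adjusted over the list alone; adjusted p = 0.668). They were called in 6 of 20 salicylate genes against 1 rise (the same adjusted over the list alone; adjusted p = 0.658). They were also called in 4 of 12 iron deficiency genes (4 adjusted over the list alone; adjusted p = 0.668) and 5 of 30 photosynthesis genes (0 adjusted over the list alone; adjusted p = 0.672). With the replicate block the raffinose and touch and wound lists were called as well (adjusted p = 0.0235 and 0.0227), but not with an estimated correlation in the fit without the block (adjusted p = 0.368 and 0.672). Plain library sizes moved the median log2 fold change of all genes from 0.0216 to 0.127. With them the split moved from 50.3% to 68.3% of calls higher, and with limma on log2(RPKM + 0.5) or log2(RPKM + 0.1) to 69.3%.

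Across the 3 genotypes, 4151 genes were called in the same direction, 2039 higher and 2112 lower, P5CS1, RD20 and PYL6 among them. WT and ahl10-1 shared 4865 calls in the same direction, WT and rrp6l1-2 4623, and the 2 mutants 4936, with 0 called in opposite directions in each case. Fold changes correlated with r = 0.933, 0.938 and 0.918 across 18641 genes, which are not independent replicates. These counts do not test a difference between genotypes.

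At control 6 genes differed between ahl10-1 and WT. The pseudogenes AT5G35935 (chromosome 5, 14083388 to 14089891) and AT3G29120 (chromosome 3, 11098505 to 11099198) were higher, by 3.07 ± 0.167 (adjusted p = 1.02e-07) and 2.41 ± 0.17 (adjusted p = 2.02e-06). AT5G35935 went from 3.5 ± 0.785 CPM in WT to 29.4 ± 2.83 CPM in ahl10-1. The non-coding RNA AT1G67105 (chromosome 1, 25057479 to 25058264) was lower, by -2.95 ± 0.343 (adjusted p = 0.00329), at 2.67 ± 0.697 CPM against 20.7 ± 2.22 CPM in WT. AT2G05914 (chromosome 2, 2263124 to 2264543), a long non-coding RNA named after its values were seen, was lower by -2.10 ± 0.285 (adjusted p = 0.00603). AT5G44925 (chromosome 5, 18142274 to 18146632), a pseudogene also named after its values were seen, had 0 reads in the 6 WT libraries and 15 to 38 reads in each ahl10-1 library (adjusted p = 0.00449 at control). In a fit of the compared groups alone AT2G05914 and AT5G44925 lost the call, and without ahl10-1 control replicate 3 AT2G05914 lost it as well. AHL10 itself was the sixth gene. Up to 20.5% of the reads of AT3G29120 were multi-mapped, so its level is uncertain.

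At stress 8 genes changed in ahl10-1, the same 6 in the same directions and another 2. AT5G35935 was higher by 3.53 ± 0.171 (adjusted p = 1.85e-08) and AT3G29120 by 2.38 ± 0.17, and AT2G05914 was lower by -2.98 ± 0.312. The further genes were SADHU3-2 (chromosome 3, 14749400 to 14750294), a non-coding retrotransposon, at -1.88 ± 0.258 (adjusted p = 0.00591), and AT5G48760, for a ribosomal protein of the L13 family, at -0.54 ± 0.0673 (adjusted p = 0.00228). In a fit of the compared groups alone both lost the call, as did AT1G67105, at -3.69 ± 0.341, and the higher AT5G44925. Without ahl10-1 stress replicate 2 SADHU3-2 (-1.75) and AT5G44925 lost it as well, and without WT stress replicate 2 AT5G44925 did.

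The 6 control calls comprised 3 higher and 3 lower and the 8 stress calls 3 higher and 5 lower, and DESeq2 called 22 and 27. At an unadjusted p under 0.05, 1355 genes passed at control and 991 at stress. These are 5.94% and 4.35% of those tested, near the share of 0.05 that unchanged genes would give in an exact test. The test may be cautious, as for the interactions below, so these shares do not show that the other genes were unchanged. Averaged over both treatments, a comparison added after the results were seen, 2386 genes (10.5%) passed unadjusted in ahl10-1. Groups did not overlap for all 6 and all 8 genes, nor for 7.73% and 11.9% of the genes tested, where chance gives 10%. Without ahl10-1 control replicate 1 the control count was 26, 11 higher and 15 lower. The authors' deposited table called 18 genes at control, including all 6 in the same direction, and the authors' deposited table for stress called 85, including all 8.

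Among the lists in ahl10-1 at control, camera called 11, and 0 were called with an estimated correlation or by fry. Besides AHL10 itself, which is on the AHL family list, 0 members were called by edgeR in any of the 11, where 1355 of all genes passed unadjusted and DESeq2 called 22. The AHL family had a median of -0.21 (camera adjusted p = 5.98e-07, and 0.398 with an estimated correlation), with 1 gene lower adjusted over the list alone. This list holds the disrupted gene and was not tested without AHL10. Touch and wound genes were at -1.42 (1.86e-05, and 0.791) and root hair genes at -0.58 (0.00747, and 0.791). Lower medians were also those of raffinose genes -0.26 (0.00914, and 0.437), meristem genes -0.12 (0.0202, and 0.791) and cell cycle genes -0.10 (0.00136, and 0.791). Wax genes stood at 0.21 (0.00493, and 0.791; 1 higher adjusted over the list alone), sulfur genes at 0.15 (0.0291, and 0.791). Photosynthesis genes stood at 0.15 (0.00136, and 0.791), aquaporins at 0.15 (0.00342, and 0.791) and auxin genes at 0.12 (0.0416, and 0.791). In each bracket the camera adjusted p is first and the p with an estimated correlation second. With RLE factors the auxin call was lost (adjusted p = 0.0609).

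At stress camera called 10 lists in ahl10-1, and 0 with an estimated correlation or by fry. Jasmonate genes had a median of 0.35 (camera adjusted p = 3.14e-05, and 0.497 with an estimated correlation), photosynthesis genes 0.21 (7.31e-06, and 0.694). Suberin genes were at 0.21 (0.0107, and 0.711), aquaporins 0.17 (0.00265, and 0.557), dehydration genes 0.15 (0.0185, and 0.84) and wax genes 0.13 (0.0107, and 0.497). Lower were meristem genes at -0.24 (0.00229, and 0.557), cell cycle genes at -0.14 (3.02e-09, and 0.497), the AHL family at -0.11 (1.67e-07, and 0.361) and exosome genes at -0.08 (0.0178, and 0.497). With edgeR, AHL10 was again the only member called, over all genes or adjusted over the list alone, where 991 genes passed unadjusted and DESeq2 called 27.

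At control 48 genes differed between rrp6l1-2 and WT, 33 higher and 15 lower. The non-coding RNAs AT4G04223 (chromosome 4, 2036511 to 2037816) and AT5G38005 (chromosome 5, 15155067 to 15156088) were higher, by 3.69 ± 0.45 (adjusted p = 0.00227) and 2.71 ± 0.225 (adjusted p = 1.6e-05). AT5G38005 went from 2.44 ± 0.291 CPM in WT to 16 ± 1.91 CPM. The pseudogenes AT5G35935, at 2.97 ± 0.166 (adjusted p = 1.63e-07), and AT3G29120, at 2.61 ± 0.171, were higher here too. Among coding genes ESM1 (AT3G14210), which favours isothiocyanate over nitrile in glucosinolate breakdown, rose by 1.09 ± 0.143 (adjusted p = 0.00227), from 469 ± 58.9 to 997 ± 34.3 CPM. AT5G26270, of unknown function, rose by 1.43 ± 0.19 and AT5G24155, an oxidoreductase gene, by 1.22 ± 0.131 (adjusted p = 0.000243). AT1G54410, AT1G54400 and RRP6L1 were lower, as given above, and so was AT1G63070, named after its values were seen, with 0 reads in 6 rrp6l1-2 libraries and in 5 of 6 ahl10-1 libraries and 17 to 48 in each WT library. Its call was lost in a fit of the compared groups alone and without WT control replicate 3 or any 1 of the rrp6l1-2 control libraries.

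At stress 19 genes changed, 14 higher and 5 lower, and 17 genes, 12 of them higher, were called at both treatments, with 0 in opposite directions. AT4G04223 was higher by 3.80 ± 0.451 (adjusted p = 0.00144; the call was lost in a fit of the compared groups alone), AT5G35935 by 3.52 ± 0.171 (adjusted p = 1.97e-08), AT3G29120 by 2.68 ± 0.171 and AT5G38005 by 2.37 ± 0.222. ESM1 rose by 1.19 ± 0.144 (adjusted p = 0.000962), AT5G26270 by 1.77 ± 0.197, and MED8, for a subunit of the Mediator complex, by 0.53 ± 0.0669 (adjusted p = 0.00144), and at control by 0.39 ± 0.0671. Up to 12.5% of the reads of AT4G04223 and 20.5% of those of AT3G29120 were multi-mapped, so their levels are uncertain.

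The count at control depended on the libraries and the fit. With the replicate block 148 genes were called, 89 higher and 59 lower, against 48 without it, and DESeq2 called 822, 565 higher and 257 lower. The block fits 1 effect per replicate number over all 6 groups, also where same-numbered libraries did not pair. In a fit of the compared groups alone 24 were called at control, 14 higher and 10 lower, and 40 at stress, 20 higher and 20 lower. Leaving out 1 library gave 20 calls at control without WT control replicate 1, 16 without WT control replicate 3, 30 without rrp6l1-2 control replicate 1 and 18 without rrp6l1-2 control replicate 3. Without ahl10-1 control replicate 1, an alternative added after seeing the data, 717 were called, 439 higher and 278 lower. Groups did not overlap for any of the 48 and 19 genes, nor for 21.9% and 14.4% of the genes tested, where chance gives 10%. The authors' deposited table called 893 genes at control, 46 of the 48 among them in the same direction, and 282 at stress, 17 of the 19 among them.

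Camera called 9 lists in rrp6l1-2 at control, and 0 with an estimated correlation. Meristem and boundary genes were lower, with a median of -0.56 (camera adjusted p = 1.59e-05, and 0.577 with an estimated correlation). With edgeR 0 members passed over all genes and 8 were lower adjusted over the list alone, including PLT1 at -1.17 ± 0.306 (adjusted p = 0.115 over all genes), KNAT1 at -0.71 ± 0.193 and PLT3 at -0.60 ± 0.176. Over all genes 4001 (17.6%) passed unadjusted and DESeq2 called 822. The AHL family stood at -0.23 (9.15e-07, and 0.268; 6 lower adjusted over the list alone), with AHL7 at -0.62 ± 0.138. Cell cycle genes stood at -0.19 (9.65e-07, and 0.577; 4 lower adjusted over the list alone), glucosinolate synthesis genes at -0.16 (0.0201, and 0.926) and exosome genes, a list that holds RRP6L1 as its only called member, at -0.08 (0.000637, and 0.268). Wax genes were higher at 0.27 (0.00264, and 0.577; 5 higher adjusted over the list alone), phosphate genes at 0.28 (0.0307, and 0.598; 2 higher adjusted over the list alone), sulfur genes at 0.26 (0.00552, and 0.598; 2 higher adjusted over the list alone) and photosynthesis genes at 0.24 (5.3e-05, and 0.926).

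At stress 9 lists were called in rrp6l1-2. Over all genes 860 (3.77%) passed unadjusted there and DESeq2 called 55. The exosome list, again with RRP6L1 as its only called member, was at -0.06 and held with an estimated correlation (adjusted p = 2.78e-07 and 0.0471). It holds the disrupted gene itself and was not tested without RRP6L1 at either treatment. Its calls therefore do not show a change of the other members. Also lower were meristem genes at -0.26 (camera adjusted p = 0.000856, and 0.825 with an estimated correlation), flavonoid genes at -0.24 (0.0498, and 0.848), the AHL family at -0.12 (0.0003, and 0.578) and cell cycle genes at -0.07 (0.003, and 0.848). Photosynthesis genes at 0.24 (6.28e-08, and 0.848), loci under DNA-methylation silencing at 0.31 (0.0498, and 0.578), wax genes at 0.18 (0.0498, and 0.848) and aquaporins at 0.14 (0.0298, and 0.848) were higher. With RLE factors the wax, flavonoid and methylation calls were lost (adjusted p = 0.0557, 0.057 and 0.0538).

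AT5G35935 and AT3G29120 were the 2 genes called in both mutants when each treatment was tested apart, higher in each at both treatments. AT5G35935 was at 26.1 to 33 CPM in the 12 mutant libraries and 1.82 to 4 CPM in the 6 WT libraries, and AT3G29120 at 4.24 to 6.33 and 0.69 to 1.1 CPM. Between the mutants, averaged over both treatments, AT5G35935 differed by -0.06 ± 0.105 (adjusted p = 0.982) and AT3G29120 by 0.25 ± 0.109 (adjusted p = 0.977). Independent lists of these sizes share 0.00434 higher and 0.00197 lower genes at control and 0.00184 and 0.0011 at stress. In turn 40 simulations of unchanged mutants shared at most 0 at control and 1 at stress. They drew the WT libraries anew as well, with 1 mean per treatment for all genotypes, and did not keep the real WT counts. Simulated calls were at most 0 for ahl10-1 and 1 for rrp6l1-2 at control, and 2 for each at stress. The covariance of the fold changes was 0.0688 at control, against 0.0469 ± 0.00513 in the simulations, a difference of 0.0219, and 0.0599 against 0.0469 ± 0.00582 at stress, a difference of 0.0130. The correlation of the fold changes was 0.449 at control, below the simulated 0.487 ± 0.0374, and 0.529 at stress against 0.494 ± 0.0456. Part of the excess in covariance may come from the shared WT libraries, since 3 cannot be split with at least 2 in each part. The simulations, which drew each count independently, do not cover structure common to many genes. DESeq2 shared 13 and 12 genes. Without ahl10-1 control replicate 1 edgeR shared 21 at control, and without WT stress replicate 1 it shared 4 at stress.

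Whether a mutation altered the response to stress was tested by the interaction. With edgeR 0 genes passed for ahl10-1 and 0 for rrp6l1-2 (smallest adjusted p = 1), and 3 and 1 by DESeq2. At an unadjusted p under 0.05 there were 316 and 383, or 1.39% and 1.68% of the genes tested. That is below the share of 0.05 that unchanged genes would give, so the test may be cautious here. The 0 calls therefore do not show that the responses were equal. The response of P5CS1 differed from that in WT by 0.23 ± 0.184 in ahl10-1 and 0.04 ± 0.184 in rrp6l1-2, and that of HAI2 by 0.83 ± 0.418 and 1.05 ± 0.442 (adjusted p = 1 in each case). The DESeq2 genes, named after their values were seen, were TPS-CIN_AT3G25830, ATCG00930 and ATCG01170 for ahl10-1 and AT2G07707 for rrp6l1-2; in some library 99.9% to 100% of the reads of these loci were multi-mapped, so they are uncertain. Without rrp6l1-2 stress replicate 1, 1 gene passed with edgeR for rrp6l1-2, AT5G39150 (-3.18, adjusted p = 0.0207), also named after its values were seen and with up to 78% of its reads multi-mapped.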

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

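The tests of the reads lost beside RRP6L1 and of ahl10-1 control replicate 1, and for the genes shared by the mutants those of paralogs and of the WT side, were chosen after the results were seen; the splits of the libraries and the simulation of shared WT libraries were not.

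By a camera test of the interaction with its preset correlation 14 gene lists were called, and all 14 calls were lost with an estimated correlation, the smallest adjusted p being 0.0561, for raffinose genes in ahl10-1, and 0.719 in rrp6l1-2, and with fry. In ahl10-1 these were the raffinose list (adjusted p = 3.46e-05, median 0.42), jasmonate (0.000689, 0.17), touch and wound (0.000751, 1.08), dehydration (0.00238, 0.21), root hair (0.00476, 0.59) and glucosinolate synthesis (0.016, 0.10). In rrp6l1-2 they were flavonoid genes (0.000135, -0.51), cell cycle (0.00122, 0.09), glucosinolate synthesis (0.00122, 0.17), sulfur (0.00323, -0.19), the AHL family (0.0036, 0.11), dehydration (0.0101, -0.13), phosphate (0.0101, -0.20) and meristem genes (0.0175, 0.17). In the raffinose list GOLS1 differed by 0.54 ± 0.134 (edgeR adjusted p = 1 over all genes; 1 member higher adjusted over the list alone). Of 40 splits of the libraries, 36 called at least as many lists as the 6 for ahl10-1 (highest other 14) and 35 at least as many as the 8 for rrp6l1-2 (highest other 15), so chance cannot be excluded for these list calls. The splits were drawn without regard to the replicate numbers, and so do not keep the pairing.

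Splits of 3 against 3 libraries number 10, too few for a share under 0.05. For genes, stress in WT gave 5941 with the real split and at most 0 with another (1 of 10 as large), ahl10-1 at stress 8 and 0 (1 of 10), rrp6l1-2 at stress 19 and 0 (1 of 10), stress in ahl10-1 6861 and 529 (1 of 10) and stress in rrp6l1-2 6733 and 0 (1 of 10). For ahl10-1 at control 6 genes stood against 1135 (2 of 10), in the split that put WT control replicates 1 and 3 and ahl10-1 control replicate 1 together, which points to a structure of the samples. For rrp6l1-2 at control 48 stood against 113 (2 of 10), with WT control replicates 1 and 2 and rrp6l1-2 control replicate 1 together. In the 3 paired comparisons the 4 splits that part 3 pairs called at most 0 genes besides the real one, and those parting 1 pair called up to 113 for rrp6l1-2 at control, 529 for stress in ahl10-1 and 0 for stress in rrp6l1-2. For the interactions all 40 of 40 splits called at least the 0 of the real one, which any split must, so this says nothing about chance. Other splits called up to 1448 genes for ahl10-1 and 82 for rrp6l1-2. For lists the real and highest other counts were 16 and 15 for stress in WT (1 of 10), 11 and 17 for ahl10-1 at control (7 of 10), 10 and 9 at stress (1 of 10), 9 and 12 for rrp6l1-2 at control (7 of 10), 9 and 10 at stress (6 of 10), 14 and 15 for stress in ahl10-1 (4 of 10) and 14 and 14 for stress in rrp6l1-2 (4 of 10).

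AT1G54400 and AT1G54410, next to RRP6L1, lost nearly all reads in rrp6l1-2. Reads shared between paralogs are argued against, since at most 0% of their reads were multi-mapped in any library. A loss or silencing of the segment next to RRP6L1 in this line stays open. Of 21131 genes with enough reads in WT and ahl10-1, 2 were at least 16-fold lower in rrp6l1-2 than in both, and these 2 were among the 22 within 50 kb of RRP6L1. Against WT alone there were 4 of 21340, and the other 2, AT1G63070 and AT3G28915, lie elsewhere and were at least 16-fold lower in ahl10-1 too. Reads from another genotype in rrp6l1-2 stress replicate 3, which held 1.25% of the WT level of AT1G54410, stay open, since that share predicts 0.568 reads of AT1G54400 and 0 were seen. A regulation of both genes by RRP6L1 was not tested and also stays open.

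AT5G35935 and AT3G29120 were called higher in both mutants. In 0 of 40 simulations were as many genes shared at either treatment. At stress this argues against chance values drawn independently for each gene. At control the simulated ahl10-1 had at most 0 calls, so no gene could be shared and nothing follows there. Chance values common to many genes of the shared WT libraries cannot be excluded, since the simulations hold none. Their mutants had at most 2 calls, while another split of the WT and ahl10-1 control libraries called 1135 genes. Reads shared between paralogs are argued against for both: without multi-mapped reads the lowest mutant library stood at 26.1 CPM for AT5G35935 and 3.73 CPM for AT3G29120, against at most 4 and 1.1 CPM with all reads in a WT library. A difference on the side of the WT libraries cannot be told apart from an effect of both mutations: the larger difference of these 2 genes between the mutants was 0.249 ± 0.109, and the design has only 1 set of WT libraries per treatment.

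Leaving out ahl10-1 control replicate 1, which is in neither compared group, raised the rrp6l1-2 calls at control from 48 to 717. A wrong label is argued against by its AHL10 level of 25.44 CPM, below every WT library, and a difference in library size by its total of 66.42 M reads (M, mega), inside the range of the others. Its share of chloroplast reads is argued against as well, since leaving out another library with at least as high a share gave at most 69 calls. No biological explanation was tested, and the reason for its distance from its group stays open.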

How the results depend on the processing

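Leaving out ahl10-1 control replicate 1 where its group is not compared was chosen after seeing the data; it sets the upper ends 717 for rrp6l1-2 at control, 28 at stress, 6373 for stress in WT and 7225 in rrp6l1-2 below. Contrasts averaged over both treatments were also added then, and the other alternatives here were planned. AHL10 and RRP6L1 kept their direction and calls in their own mutants under every alternative run: without 1 library AHL10 ranged from -1.09 to -0.95 at control and -1.17 to -1.04 at stress, and RRP6L1 from -2.08 to -1.75 and -2.70 to -2.30. Among targets and extreme genes, 1236 values were the same, 71 weaker, 0 stronger and 2 moved, and among list members 12384 were the same, 292 weaker, 69 stronger and 94 moved, with 0 reversed.

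A minimum log2 change of 1 left 1630 genes for stress in WT, 1723 in ahl10-1 and 1556 in rrp6l1-2 and 23 for rrp6l1-2 at control, by construction. The cause was not tested for the following. DESeq2 called 22 and 27 genes for ahl10-1 at control and stress, 822 and 55 for rrp6l1-2, 3 and 1 for the interactions of ahl10-1 and rrp6l1-2, and 13 and 12 in the overlap at control and stress. On the simulated data DESeq2 made more false calls than edgeR: 46 among 220 against 13 among 181 for ahl10-1 at control, 37 among 210 against 4 among 167 at stress, 36 among 207 against 8 among 163 for rrp6l1-2 at stress and 29 among 174 against 2 among 132 for its interaction. With no change planted it made 13 against 1 for rrp6l1-2 at control and 5 against 0 for the ahl10-1 interaction. A fit of only the groups compared, with fewer libraries, gave 5 for ahl10-1 at stress and 24 and 40 for rrp6l1-2 at control and stress. For rrp6l1-2 at control limma on log2(RPKM + 0.5) and log2(RPKM + 0.1) gave 28 and 26, and the replicate block 148. The block changed no other gene count by over 1.5 times except that of rrp6l1-2 averaged over both treatments, 576 against 189. For the paired stress comparisons it gave 7616 genes in ahl10-1, against 6861, and 7614 in rrp6l1-2, against 6733. With it stress in WT gave 6725 genes and 15 lists, losing the iron list (camera adjusted p = 0.0779), and ahl10-1 7 and 9 and rrp6l1-2 at stress 17. Same-numbered libraries did not pair in the other comparisons, with correlations of -0.0656 to 0.041 for stress in WT, -0.323 to 0.435 and -0.147 to 0.156 for ahl10-1 at control and stress, and -0.157 to 0.261 for rrp6l1-2 at stress. There 0, 2, 0 and 1 of the 3 numbers, in that order, correlated best with their own, a hint from the data and not the design.

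With an estimated correlation camera called 2 lists for stress in WT, 4 in ahl10-1 and 1 in rrp6l1-2, 0 and 0 for ahl10-1 at control and stress, 0 and 1 for rrp6l1-2, and 0 and 0 for the interactions. The 1 for rrp6l1-2 against WT at stress is the exosome list, which holds RRP6L1 itself. Fry called 0 and 0 for ahl10-1, 2 and 1 for rrp6l1-2 and 0 and 0 for the interactions. Without 1 library the counts ran from 6 to 26 for ahl10-1 at control, 16 to 717 for rrp6l1-2 at control, 0 to 1 for its interaction, and 2 to 21 and 2 to 4 for the overlap at control and stress. They ran from 4239 to 6373 for stress in WT, 5122 to 6764 in ahl10-1 and 4819 to 7225 in rrp6l1-2, and from 6 to 10 and 13 to 28 for the mutants at stress. Depth limits genes such as AT1G54400, where 0 reads allow up to 3.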

Other observations

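The contrasts averaged over both treatments, their alternatives and the test of gene types were chosen after the results were seen.

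Averaged over both treatments, edgeR called 18 genes in ahl10-1 against WT, 9 higher and 9 lower, 189 in rrp6l1-2, 133 higher and 56 lower, and 47 between the mutants, 34 higher and 13 lower in rrp6l1-2. DESeq2 called 111, 1345 and 106 in that order, the stricter filter 11, 102 and 27, and for rrp6l1-2 the replicate block gave 576. Both mutants shared 13 of these edgeR calls, 8 higher and 5 lower. Independent lists of these sizes share 0.0525 and 0.0221. The 40 simulations of unchanged mutants shared at most 0. Each simulated mutant had at most 1 call, so 13 could not be shared there and nothing follows from that 0. The replicate block gave 12 shared genes, the stricter filter 6 and DESeq2 77, and part of the sharing may come from the shared WT libraries. Structure common to many genes is not covered by these simulations. Among the 13, AT4G04223 was higher in ahl10-1 by 2.32 ± 0.31 and AT5G38005 by 1.17 ± 0.156, while AT1G67105 was lower by -3.32 ± 0.242 in ahl10-1 and -1.22 ± 0.219 in rrp6l1-2 and AT2G05914 by -2.54 ± 0.212 and -0.88 ± 0.193. AT1G63070, lower in both, had 198 reads in WT, 2 in ahl10-1 and 0 in rrp6l1-2, too few for a fold change. LBD26, a gene of the lateral organ boundaries family, was higher in rrp6l1-2 by 1.91 ± 0.218 at control (adjusted p = 0.00044) and 1.88 ± 0.217 at stress (adjusted p = 0.000612), while in ahl10-1 it was at -0.22 ± 0.224 and -0.50 ± 0.224 (adjusted p = 0.886 and 0.996). AT4G04223 and AT5G38005, higher in rrp6l1-2, stood at 7.07 ± 3.98 and 5.38 ± 1.57 CPM in ahl10-1 at control, between 1.66 ± 0.614 and 2.44 ± 0.291 CPM in WT and 21.5 ± 1.56 and 16 ± 1.91 CPM in rrp6l1-2. AT5G44925, with 0 reads in WT, had 4 to 16 reads in each rrp6l1-2 library. LBD26 and the genes named here as shared were chosen after their values were seen.

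A hypothesis was that RNAs that do not code for protein are higher where RRP6L1 is low. Of the 22555 genes tested that have an annotated type, 918 (4.07%) do not code for protein. Among genes higher in rrp6l1-2 over both treatments it was 27 of 133 (20.3%, Fisher exact adjusted p over 6 tests = 2.31e-11), and among those lower 7 of 55 (12.7%, adjusted p = 0.00669). These shares depend on the list of calls: with the replicate block they were 36 of 365 higher (9.86%, adjusted p = 2.44e-06) and 13 of 207 lower (6.28%, adjusted p = 0.11), and with DESeq2 42 of 903 (4.65%, adjusted p = 0.345) and 23 of 435 (5.29%, adjusted p = 0.262), where the excess in rrp6l1-2 was lost. In ahl10-1 it was 6 of 9 higher (66.7%, adjusted p = 6.76e-07) and 4 of 9 lower (44.4%, adjusted p = 0.000437), with the replicate block 6 of 10 (60%, adjusted p = 2.44e-06) and 3 of 8 (37.5%, adjusted p = 0.00387), and with DESeq2 10 of 66 (15.2%, adjusted p = 0.000633) and 5 of 43 (11.6%, adjusted p = 0.0444), so the excess cannot be tied to RRP6L1. Between the mutants it was 13 of 34 higher in rrp6l1-2 (38.2%, adjusted p = 9.73e-10) and 4 of 12 lower (33.3%, adjusted p = 0.00125), with the replicate block 13 of 34 (38.2%, adjusted p = 1.95e-09) and 5 of 13 (38.5%, adjusted p = 0.000162), and with DESeq2 22 of 76 (28.9%, adjusted p = 1.09e-12) and 8 of 25 (32%, adjusted p = 1.28e-05).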
